A study of Mus musculus with 4 samples.

How the data were processed

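Single-cell RNA sequencing was done on cells of NXS-2 neuroblastomas from female A/J mice aged 4 to 6 weeks, treated with vehicle, hu14.18-IL2, hu14.18-IL15 or hu14.18-IL21. Per the labels' protocols, tumors were made into cell suspensions, CD45-bearing cells were selected on magnetic beads, cells of 3 mice per group were pooled, about 10000 cells were loaded to capture 6000, and libraries were made with the 10x Genomics 3′ v3.1 chemistry and sequenced on a NextSeq 2000 toward 50000 reads per cell. The bead selection and tumor size can set how many tumor cells each library held, so shares were taken over leukocytes.

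The deposited files are filtered matrices of raw UMI counts per gene and barcode, not normalized, for 32285 genes and 30795 barcodes. Per the submitters' processing notes, reads were processed with Cell Ranger 2.1.1 against mm10, and the gene annotation release is not given in the sources used here. UMIs of near-identical genes, such as Ly6c1 and Ly6c2, Ifit3 and Ifit3b or the histone and H2 families, may be split between copies, and a 3′ count does not separate isoforms. Gene coordinates are 1-based spans in GRCm38 from GENCODE M21, matched on the Ensembl identifiers of the files, and every gene given with coordinates is annotated as protein coding.

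Cells with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept: 4007 in vehicle, 6221 after hu14.18-IL2, 7866 after hu14.18-IL15 and 6782 after hu14.18-IL21. Scrublet, as included in scanpy 1.11.5, was run per library and its calls were left out. It called 247, 223 and 231 cells in the treated libraries but 4 in vehicle, so the vehicle call had not worked. One score limit for all libraries, 0.239, was therefore tried after the data were seen. Cells were scaled to a common total and log-transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components, 15 neighbours and Leiden resolution 1.0 gave the clusters. T and NK cells were clustered again on their own. Genes of the response lists, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor variable genes were left out of the clustering genes. Ly6c1 and Ly6c2, which lead T4, were not left out.

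Clusters were named "-like" from markers fixed before the data were examined. A cluster stayed unnamed where doublet calls, mixed lineages or few detected markers spoke against a name, with limits set after they were looked at. The unnamed clusters were 14, with 5.23%, 4.27%, 5.52% and 4.01% of leukocytes in vehicle and after the IL2, IL15 and IL21 fusions, and T11, with 1.20%, 0.809%, 1.61% and 2.65%. The unnamed clusters outside leukocytes together held 2.92%, 1.74%, 3.76% and 4.56% of kept cells. A mixed CD4 and CD8 class held 4.84%, 3.72%, 5.84% and 6.87% of leukocytes. Its genes were not compared, and its share differences appear only among the alternatives. Leading genes of T and NK clusters were first ranked against the other T and NK clusters. That left T1 unnamed and gave T4 2 monocyte markers against 1 of its own among its top 10, which would bar CD8 T-like cells from being compared as a class. Ranking them against clusters outside T and NK cells was used instead, a choice made after both were seen, and the shares of the 6 CD8 clusters are given too. Cluster T9, macrophage clusters 5 and 6 and neuroblastoma clusters 12, 13, 16 and 23 had 0 markers of their own class among their top 10 genes, though 6 to 12 were detected.

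Shares carry exact Clopper-Pearson intervals and differences Newcombe intervals, all at 95%. Within a class, raw counts were summed per library and given as CPM of the class total with exact Poisson intervals, and log2 ratios of treatment over vehicle had 1 added to each sum. A ratio against 0 UMIs is given as a bound, with 3 UMIs put in the place of 0 in that library. A class was compared where both libraries held at least 50 of its cells, which left out neutrophil-like, B-like and conventional DC 1-like cells and, for hu14.18-IL15, CD4 T-like cells. A gene was measured from 20 UMIs in the larger sum. For a list the median log2 ratio is given with a counting interval, the number of members at least 1.5-fold higher or lower, and the percentile of the median among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries and is not a test.

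Named genes were, per comparison and class, the 3 highest and 3 lowest log2 ratios among genes with at least 50 UMIs and 20 CPM in the larger sum, after leaving out mitochondrial, ribosomal, haemoglobin, immunoglobulin, receptor segment and unnamed genes, Xist, markers of other classes and genes under 1/10 of their level in another class of that library. Added to these were members of each list with the largest ratios and a fixed set (Foxp3, Il2ra, Gzma, Gzmb, Prf1, Ifng, Mki67, Pdcd1, Cxcl9, Nos2, Arg1, Mrc1, Cd274, Socs3, Cish, Fcgr1, Fcgr4 and Il10). Chosen after their values were seen were C1qa and Apoe in macrophage-like cells and, as gauges of RNA from other cells, Igkc, Jchain, Hbb-bs and Mfge8. The NK, CD8, regulatory T, macrophage, monocyte and neutrophil shares were planned, and the plasma, plasmacytoid DC and CD4 T shares were added once cell numbers were seen, and the interferon list in NK-like and regulatory T-like cells once its values were. The number of cells holding a gene's UMIs was counted after the data were seen.

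The lists were cytotoxic effectors, cell cycle, type I interferon response, interferon-gamma response, MHC class I and class II presentation, inhibitory receptors and exhaustion, naive and memory T cell genes, regulatory T cell effectors, STAT5 targets, STAT3 targets, cytokine receptors and ligands, M1-type and M2-type macrophage genes, suppressive myeloid genes, Fc receptors and phagocytosis, chemokines, complement and lipid handling, glycolysis and hypoxia, dissociation and stress, and ribosomal protein genes. All were fixed before the data were examined.

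The steps were tested on simulated counts drawn from the vehicle means with known folds. Of 100 genes made 2-fold higher or lower, 99.0% came within 0.5 log2 units in CD8 T-like cells (10079 genes measured), 94.0% in NK-like cells (5592 genes) and 97.0% in macrophage/monocyte-like cells (10883 genes). Among unchanged genes 3.25%, 14.3% and 2.75% went beyond 1.5-fold.

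The alternatives fixed before the data were examined were doublet calls kept, a stricter filter (500 genes, 1000 UMIs, 5% mitochondrial), resolutions 0.6 and 1.6, response genes kept, each library clustered on its own, all kept cells as denominator, scaling by the median ratio, cells weighted equally, other UMI minimums, 10 added to each sum, and thinning to 2000 UMIs or none in place of 1000. Those added after the data were seen were the single doublet limit, the other ranking of leading genes, gene values, all shares and the CD8 to regulatory T ratio without T4, T12, T3, cluster 3 or clusters 5 and 6 where these bear on them, and the tumor share with clusters 12, 13, 16 and 23 not counted as tumor or left out altogether. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12, scikit-learn 1.9.0 and matplotlib 3.10.9, with seed 1.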

Results

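Single-cell RNA sequencing was used to describe the cells of orthotopic neuroblastomas after 1 dose of an immunocytokine. The tumors were grown from NXS-2, a mouse neuroblastoma line that displays the disialoganglioside GD2, in female A/J mice. Each immunocytokine joins hu14.18, a humanized antibody against GD2, to IL-2, IL-15 or IL-21, cytokines whose receptors share the common gamma chain. Mice received vehicle or 25 µg of hu14.18-IL2, hu14.18-IL15 or hu14.18-IL21 into a vein, and tumors were taken about 48 h later. Cells bearing CD45, a surface protein of leukocytes, were enriched with magnetic beads before 10x Genomics 3′ libraries were made. Each group had 1 library from a pool of 3 mice, so the 4 libraries allow 3 comparisons with vehicle and have no replicates. No test between groups was possible, no p-value is given, and every interval below covers counting error only.

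The libraries held 69558062 UMIs over 5901 barcodes in vehicle, 79050846 over 7767 after hu14.18-IL2, 107811837 over 9300 after hu14.18-IL15 and 94914455 over 7827 after hu14.18-IL21. After the cell filters and doublet calls, 4003, 5974, 7643 and 6551 cells remained, in the same order, with a median of 8360, 10537, 12306 and 11272 UMIs per cell. Barcodes above the mitochondrial limit numbered 1758 in vehicle, 1499 after hu14.18-IL2, 1415 after hu14.18-IL15 and 1013 after hu14.18-IL21.

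Cells with the transcripts of neuroblastoma were 13.5% of the kept cells in vehicle (95% exact interval 12.5 to 14.6), 46.5% after hu14.18-IL2, 58.8% after hu14.18-IL15 and 43.6% after hu14.18-IL21. Of these cells 30.1%, 70.1%, 71.3% and 78.4%, in the same order, lay in clusters 12, 13, 16 and 23. These had 0 neuroblastoma markers among their top 10 genes but 7, 8, 6 and 8 detected, against 11 in clusters 9 and 11. In alternatives chosen after the data were seen, the cells of the other clusters were 9.44% (8.55 to 10.4), 13.9%, 16.9% and 9.40% of all kept cells, and 9.84% (8.92 to 10.8), 20.6%, 29.1% and 14.3% (13.3 to 15.4) once cells of those 4 clusters were left out of the denominator too. Cell class shares are therefore given as shares of leukocytes, of which there were 3345 in vehicle, 3091 after hu14.18-IL2, 2860 after hu14.18-IL15 and 3394 after hu14.18-IL21. Free RNA also differed between libraries: Mfge8, at 107 CPM in vehicle tumor-like cells and 963 to 2075 CPM in treated ones, stood at 4.47 CPM in vehicle CD8 T-like cells and at 27.1 to 47.6 CPM in treated ones. Igkc, an antibody gene of plasma cells, stood in NK-like cells at 382 CPM in vehicle and at 124, 215 and 688 CPM after the IL2, IL15 and IL21 fusions. In CD8 T-like cells it stood at 311 CPM in vehicle and at 118, 1018 and 641 CPM after treatment, and Jchain, also of plasma cells, at 14.0, 2.85, 89.8 and 16.5 CPM, but 80.8% and 91.5% of their UMIs after hu14.18-IL15 lay in 5 cells. The haemoglobin gene Hbb-bs was there at 543 CPM in vehicle, with 96.5% of its UMIs in 5 cells, and at 8.72, 3.26 and 4.85 CPM after treatment.

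**Figure D1:**
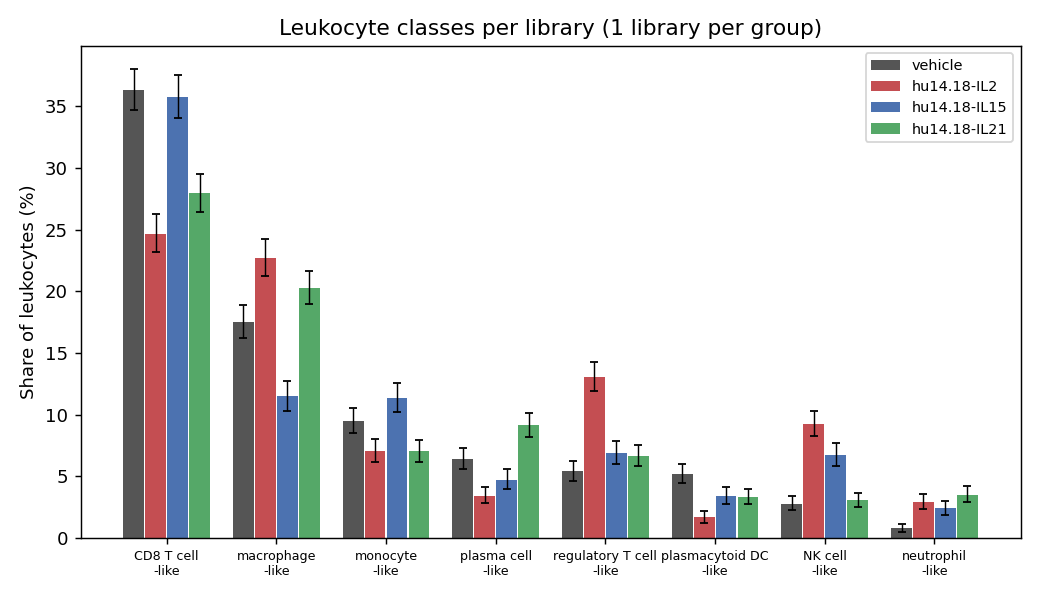
Bars give each of 8 cell classes as a percent of leukocytes in the vehicle, hu14.18-IL2, hu14.18-IL15 and hu14.18-IL21 libraries, and error bars are 95% exact binomial intervals that cover counting error only. NK-like cells stand at 2.78% in vehicle and 9.22% after hu14.18-IL2, and regulatory T-like cells at 5.38% and 13%.

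The CD8 T-like class was made of 6 clusters, and the libraries filled them differently. Cluster T4 held 23.1% of vehicle leukocytes (21.7 to 24.6), which is 772 of the 1216 vehicle CD8 T-like cells, against 1.07% after hu14.18-IL2, 2.48% after hu14.18-IL15 and 2.74% after hu14.18-IL21. Within T and NK cells its leading genes were Ly6c1, Ly6c2, Cxcr6, Cd226, Plac8 and Ifit1, and a cluster that comes mostly from 1 library may be that library rather than a cell type. The treated CD8 T-like cells lay mostly in T2, T5 and T10: T5, led by Havcr2, Prf1 and Ccl5, held 2.54% of leukocytes in vehicle and 5.34%, 10.7% and 11.5% after the IL2, IL15 and IL21 fusions. T2, led by DNA replication genes such as Cdc6 and Mcm3, and T10, led by histone genes, held 2.48% and 4.96% in vehicle, 6.92% and 8.86% after hu14.18-IL2, 9.06% and 10.1% after hu14.18-IL15, and 4.66% and 5.60% after hu14.18-IL21. T8 held 1.70%, 1.42%, 2.62% and 1.15% and T9 1.58%, 1.07%, 0.874% and 2.36%, with vehicle first. Values within CD8 T-like cells, and shares of every class, are therefore followed by the value without T4 wherever it turned or moved by more than 1.5 times, an alternative chosen after the data were seen. For shares, the cells left out were taken from both the class and the leukocytes. With T4 kept among the leukocytes, CD8 T-like cells outside T4 were 13.3% of them in vehicle and 23.6%, 33.3% and 25.2% after treatment. Regulatory T-like cells were T7 and T3, a cluster led by histone genes and Tyms. T3 held 59 of 180 cells and 71.4% of UMIs in vehicle, 148 of 403 and 62.3% after hu14.18-IL2, 56 of 196 and 58.1% after hu14.18-IL15, and 45 of 225 and 45.7% after hu14.18-IL21. Macrophage/monocyte-like cells were macrophage clusters 4 to 6 and monocyte cluster 3, which held 35.1% of them in vehicle and 23.6%, 49.7% and 25.7% after treatment. Values without T3 or cluster 3 are added for these classes by the same rule.

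**Figure D2:**
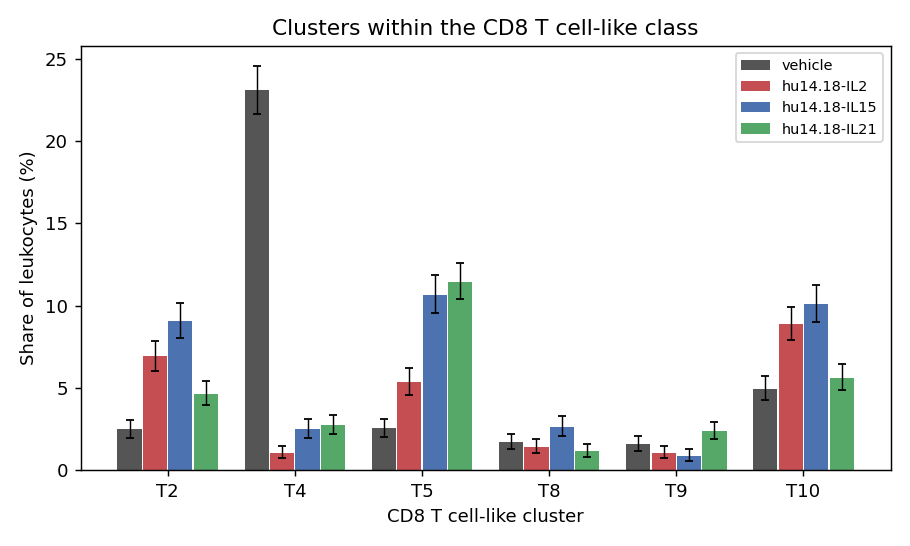
Bars give the 6 CD8 T-like clusters T2, T4, T5, T8, T9 and T10 as a percent of leukocytes in each of the 4 libraries, with 95% exact binomial intervals for counting error. T4 stands at 23.1% in vehicle and at 1.07% to 2.74% in the treated libraries.

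The comparison of hu14.18-IL2 with vehicle asks how the leukocytes of the tumor differ 48 h after the antibody carrying IL-2. NK-like cells were 9.22% of leukocytes (8.22 to 10.3, 285 cells) against 2.78% in vehicle (2.25 to 3.40, 93 cells), 3.32-fold higher, with a difference of 6.44 percentage points (Newcombe interval 5.29 to 7.62). Regulatory T-like cells, the suppressive Foxp3 lineage, were 13% (11.9 to 14.3) against 5.38% (4.64 to 6.20), 2.42-fold higher, a difference of 7.66 points (6.25 to 9.08), or 4.98 without T3. CD8 T-like cells were lower, at 24.7% against 36.4%, a difference of -11.7 points (-13.9 to -9.43) that turned to 6.62 (4.50 to 8.71) without T4. The ratio of CD8 T-like to regulatory T-like cells was 1.89 (1.68 to 2.14) against 6.76 (5.77 to 7.95), or 1.81 (1.6 to 2.05) against 2.47 (2.07 to 2.95) without T4 and 2.99 against 10.05 without T3. Over all kept cells the NK-like, regulatory T-like and CD8 T-like differences were 2.45, 2.25 and -17.6 points. Within these classes, cell cycle genes were higher in NK-like cells. Type I interferon-response genes were lower in CD8 T-like, macrophage/monocyte-like, NK-like and regulatory T-like cells. Their median log2 ratio in NK-like cells was -0.83 (-1.09 to -0.59, percentile 0, 13 of 19 lower), or -1.27 from 1 UMI and -0.49 from 100 UMIs, and in regulatory T-like cells -0.50 (-0.62 to -0.37, percentile 0, 1 higher and 11 lower of 28), or -1.11 without T3 and -0.79 with cells weighted equally.

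Macrophage-like cells were 22.7% of leukocytes after hu14.18-IL2 against 17.5% in vehicle, a difference of 5.23 points (3.27 to 7.19), and monocyte-like cells 7.02% against 9.48%, a difference of -2.46 points (-3.80 to -1.11). The macrophage difference was -2.87 points when all kept cells were the denominator, 1.95 with each library clustered on its own, 8.17 under the stricter filter and 0.214 (-1.99 to 2.41) without T4, and the monocyte difference -4.29, -0.711 and -5.22 in the first 2 and the last of these. CD4 T-like cells were 3.40% against 2.36%, a difference of 1.04 points (0.219 to 1.87) that was -0.216 over all kept cells, -0.840 with response genes kept and 0.363 without T4. Plasma-like cells, at 3.40% against 6.43%, differed by -3.03 points (-4.09 to -1.98), or -4.92 without T4, and plasmacytoid DC-like cells, a main source of type I interferon, at 1.65% against 5.20%, by -3.55 points (-4.45 to -2.68). Neutrophil-like cells were 2.91% against 0.777%, a difference of 2.13 points that was -0.200 under the stricter cell filter and 0.857 over all kept cells.

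In NK-like cells 37 of the 39 measured cell cycle genes were at least 1.5-fold higher after hu14.18-IL2 and 0 were as much lower. Their median log2 ratio was 2.94 (2.64 to 3.49), at percentile 100 of 10000 random lists matched on expression, and 2.48 with the 7 genes absent from vehicle set at their bound. Mki67, the proliferation antigen, was at 455 CPM against 9.17, log2 ratio 5.22 (3.85 to 7.10), and the histone gene Hist1h2ae at 513 against 9.17 CPM, log2 ratio 5.39 (4.03 to 7.28), or 1.06 without cluster T12. Cdca8 (ENSMUSG00000028873, chromosome 4, 124918465 to 124939311), a subunit of the chromosomal passenger complex of mitosis, was at 192 CPM with 0 UMIs in vehicle, at least 20.9-fold higher, and the kinetochore motor gene Cenpe was at least 14.0-fold higher, but 9 of 184 Cdca8 and 9 of 123 Cenpe UMIs lay outside T12. Cluster T12, with 58 cells after hu14.18-IL2 and 0 in vehicle, held much of this: without it the list median was 0.74 over 17 measured genes, and Mki67 was at 2.06.

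The cytotoxic effector list stood near vehicle in NK-like cells after hu14.18-IL2, with a median of 0.09 (-0.01 to 0.25) at percentile 53.8, or 0.14 without T12, and 4 of 19 genes higher and 3 lower. The median over all measured genes was -0.25 in this comparison, and relative to it the cytotoxic median was 0.34. Ccl3, a chemokine for macrophages and T cells, was at 140 against 15.3 CPM, log2 ratio 2.94 (1.78 to 4.41). Ifng was at 72.1 against 27.5 CPM, log2 ratio 1.26 (0.29 to 2.38), and the granzyme gene Gzma at 8870 against 6728 CPM, log2 ratio 0.40 (0.33 to 0.47). Prf1, encoding perforin, was at 696 against 700.0 CPM, log2 ratio -0.01, or 0.24 without T12. The interferon-induced Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960), the mitochondrial leucyl-tRNA synthetase gene Lars2 and the ubiquitin ligase gene Mylip were the lowest by the naming rule, at log2 ratios of -2.87 (-3.59 to -2.19), -1.93 and -1.93. STAT3 targets had a median of -0.65 (-0.89 to -0.31, percentile 0.210, 2 higher and 7 lower of 12), or -0.40 without T12, with Stat3 itself at -1.11 and Junb at -1.07, or -0.67 without T12. STAT5 targets stood at -0.39 (-0.57 to -0.17, percentile 1.35, 1 higher and 4 lower of 12), with -0.15 outside T12, and included Bcl2 at -1.17 and Ccnd2 at -1.09, both at -0.73 outside T12. Receptors and ligands of the IL-2, IL-15 and IL-21 system stood at -0.54 (7 genes, percentile 0.665), or -0.28 without T12, dissociation and stress genes at -0.49 (16 genes, percentile 0.290) and ribosomal protein genes at 0.23 (20 genes, percentile 83.6).

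In CD8 T-like cells all 32 measured type I interferon-response genes were at least 1.5-fold lower after hu14.18-IL2, with a median log2 ratio of -2.05 (-2.22 to -1.81) at percentile 0. Without T4 the median was -1.40, with 27 of 30 genes lower. Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), an antiviral effector, was at 1.6 against 44.8 CPM, log2 ratio -4.66 (-5.73 to -3.76), followed by Ifi206 at -4.26 and Ifit1 at -4.00. MHC class I presentation genes had a median of -0.74 (-0.81 to -0.71, percentile 0, 11 of 17 lower), or -0.46 without T4, with the nonclassical class I gene H2-T22 at -1.57, or -1.01 without T4. Inhibitory receptor and exhaustion genes stood at -0.60 (-0.71 to -0.44, percentile 0.060, 9 of 17 lower) and at -0.39 without T4, among them the checkpoint receptor Lag3 at -1.18. Pdcd1, encoding PD-1, was at -0.18, or 0.07 without T4.

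Cell cycle genes in CD8 T-like cells were higher by a median of 0.47 (0.43 to 0.53, percentile 100, 13 of 40 higher) after hu14.18-IL2, and stood at -0.20 without T4. The cytotoxic list stood at -0.21 (-0.42 to -0.06, percentile 4.70, 7 higher and 8 lower of 24) and at -0.08 without T4. Gzmb was at 476 against 452 CPM, Prf1 at 513 against 508.5 and Ifng at 165 against 235 CPM, log2 ratios of 0.08, 0.01 and -0.51 that were 0.39, 0.32 and -0.06 without T4. Gzma was at 56.4 against 4.77 CPM, log2 ratio 3.54 (3.1 to 4.01), in 60 of 763 cells, with 65.6% of its UMIs in 5 of them. Il2ra, the high-affinity IL-2 receptor chain CD25, was at 14.4 against 1.83 CPM, log2 ratio 2.92 (2.19 to 3.72), in 59 cells. The metal-binding genes Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) and Mt1 and the threonine catabolism gene Gcat were the highest by the naming rule, at 2.66, 2.24 and 1.77, the last at 1.14 without T4. STAT5 targets stood at -0.01 (24 genes, percentile 76.7), or 0.24 without T4, and STAT3 targets at -0.21 (16 genes, percentile 23.8), or -0.11 without T4. Naive and memory genes stood at -0.52 (14 genes, percentile 2.01), stress genes at -0.31 (20 genes, percentile 3.00) and ribosomal protein genes at 0.15 (20 genes, percentile 70.7), or 0.06 without T4.

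In regulatory T-like cells Foxp3, the lineage regulator, was at 156 CPM after hu14.18-IL2 and 153 CPM in vehicle, log2 ratio 0.02, or -0.39 without T3. Il2ra was at 73.8 against 104.5 CPM, log2 ratio -0.50 (-0.80 to -0.20), or -0.83 without T3. Effector genes of this lineage had a median of -0.22 (-0.32 to -0.13, percentile 2.32, 3 higher and 3 lower of 22), or -0.44 without T3, and STAT5 targets -0.23 (percentile 1.46, 1 higher and 4 lower of 23), or -0.45 without T3. Cell cycle genes stood at -0.12 (-0.16 to -0.02, percentile 5.66, 2 of 40 lower), but at 0.23 without T3 and at 0.24 when cells were weighted equally. Il10, encoding a suppressive cytokine, was at 23.2 against 7.26 CPM, log2 ratio 1.61 (0.78 to 2.52), or 0.89 without T3. Gzmb was at 172 against 85.6 CPM, log2 ratio 1.00 (0.74 to 1.27), and Ifng at 58.8 against 18.4 CPM, log2 ratio 1.65 (1.12 to 2.21). These stood at 0.39 and 0.45 without T3. The leukotriene B4 receptor gene Ltb4r1 (ENSMUSG00000046908, chromosome 14, 55765962 to 55768494) and Klf3 were also high, at 2.21, or 1.17 without T3, and 1.68. Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), an immediate early gene, was at -2.1 (-2.75 to -1.49), or -1.07 without T3. Tcf7, a regulator of naive and memory T cells, was at -1.96 (-2.57 to -1.38), or -0.49 without T3, and Ifit1 at -1.70, and 55.2% of the vehicle Tcf7 UMIs came from 5 of 180 cells.

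In macrophage/monocyte-like cells 28 of 33 type I interferon-response genes were at least 1.5-fold lower after hu14.18-IL2, with a median of -1.0 (-1.06 to -0.92) at percentile 0, among them Isg20 at -2.20, or -1.44 without cluster 3, and Ifit1 at -1.81. Interferon-gamma response genes stood at -0.01 (-0.03 to 0.07, percentile 4.84, 2 higher and 5 lower of 35), or 0.01 without clusters 5 and 6 and 0.28 without cluster 3 (percentile 94.1, 10 higher and 3 lower of 34), with the T cell chemokine Cxcl9 at 0.54, or 1.13 without cluster 3. Complement and lipid-handling genes had a median of -0.87 (-0.90 to -0.84, percentile 0, 15 of 22 lower), or -1.02 in macrophage-like and -0.25 in monocyte-like cells alone, but C1qa, a complement gene among them, stood at 0.29 in macrophage-like cells. The fatty acid carrier Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576) was at 19.9 against 334 CPM, log2 ratio -4.06 (-4.31 to -3.82). Gpnmb was at -3.79, the vacuolar pump gene Atp6v0d2 at -3.90 and the lysosomal protease Ctsl at -2.51. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, was at 3.48 against 52.5 CPM, log2 ratio -3.86 (-4.49 to -3.30), with UMIs in 11 treated and 101 vehicle cells. The haemoglobin scavenger receptor Cd163 was at 43.1 against 5.25 CPM, log2 ratio 3.02 (2.64 to 3.42), the scavenger receptor Stab1 at 2.85 and Adamdec1 (ENSMUSG00000022057, chromosome 14, 68563380 to 68582095) at 4.90 (4.06 to 5.88). Cxcl13, a B cell chemokine, was at -3.86 and at -0.50 without clusters 5 and 6, and 89.9% of its vehicle UMIs came from 5 cells.

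MHC class II genes in these cells had a median of -0.46 (-0.58 to -0.42, percentile 0.035, 3 of 11 lower) after hu14.18-IL2, with H2-Aa at 3177 against 5103 CPM. Inflammatory (M1-type) genes stood at -0.10 (-0.22 to -0.04, percentile 4.05, 4 higher and 6 lower of 19), or -0.03 without clusters 5 and 6 and 0.03 without cluster 3. Alternatively activated (M2-type) genes stood at 0.14 (0.01 to 0.23, percentile 69.1, 7 higher and 7 lower of 24), or 0.03 without those clusters. Arg1, encoding the arginine-degrading enzyme arginase, was at 0.73, but at -1.16 without those clusters. Suppressive myeloid genes stood at 0.45 (0.16 to 0.51, percentile 99.97) and at 0.04 without clusters 5 and 6, with S100a8 at 2.90, of whose UMIs 58.0% came from 5 cells. Fc receptor and phagocytosis genes stood at -0.10 (20 genes, percentile 1.24), or -0.03 without them, with Fcgr1 at -0.10, or 0.25 without cluster 3, and Fcgr4 at -0.10, or 0.16 without clusters 5 and 6 and -0.16 without cluster 3. Chemokine genes stood at 0.14 (21 genes, percentile 67.6), at -0.07 without those clusters, at 0.39 without cluster 3 and at -0.26 with cells weighted equally. Glycolysis and hypoxia genes stood at 0.37 (23 genes, percentile 99.95), or 0.25 at percentile 90.7 without those clusters. Stress genes stood at -0.02 (23 genes, percentile 12.2), or -0.08 without them and 0.18 without cluster 3, and ribosomal protein genes at 0.34 (20 genes, percentile 99.8). The NK-like values rest on 93 vehicle cells, and the pool of mice and the treatment cannot be separated in any of these differences.

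**Figure D3:**
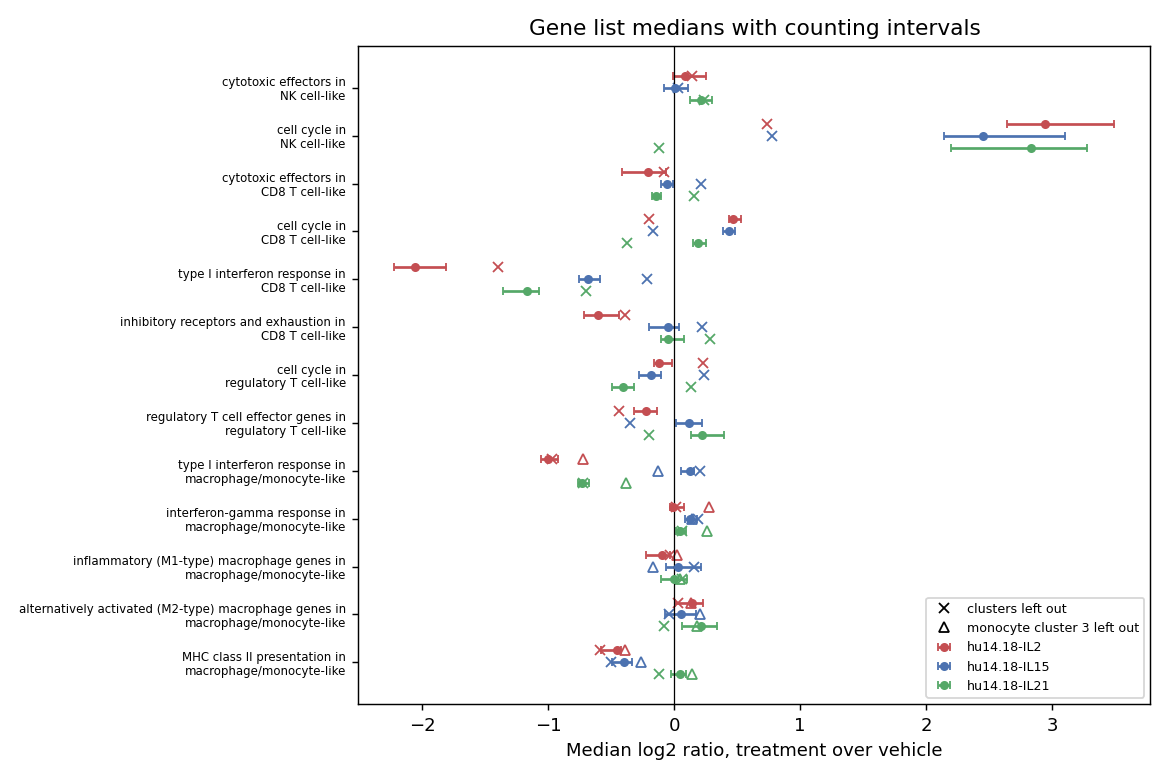
Points give the median log2 ratio of treatment over vehicle for 13 class and gene list pairs in each of the 3 comparisons, bars are 95% counting intervals, and crosses show the value with clusters T4 (CD8 T-like), T12 (NK-like), T3 (regulatory T-like) or 5 and 6 (macrophage/monocyte-like) left out, and triangles without monocyte cluster 3. The type I interferon list in CD8 T-like cells stands at -2.05 after hu14.18-IL2, -0.68 after hu14.18-IL15 and -1.17 after hu14.18-IL21, and the NK-like cell cycle list at 2.94, 2.45 and 2.83.

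The comparison of hu14.18-IL15 with vehicle asks the same of the antibody carrying IL-15, a cytokine that maintains NK and memory CD8 T cells. NK-like cells were 6.75% of leukocytes (5.86 to 7.73, 193 cells) against 2.78% in vehicle, 2.43-fold higher, a difference of 3.97 points (2.91 to 5.07) that was 0.202 over all kept cells. CD8 T-like cells were at 35.8% (34.0 to 37.6) against 36.4% (34.7 to 38.0), a difference of -0.549 points (-2.94 to 1.85), and Gzmb was 776 against 452 CPM in them. That difference was 3.81 with each library clustered on its own, 1.2 and -2.56 at clustering resolutions of 1.6 and 0.6, -0.989 under the stricter filter, -0.900 with response genes kept, -17.0 over all kept cells and 16.9 (14.6 to 19.2) without T4. Regulatory T-like cells were 6.85% (5.95 to 7.84) against 5.38%, a difference of 1.47 points (0.279 to 2.69) that became -1.93 points over all kept cells, 0.918 under the stricter filter and 0.0319 (-1.35 to 1.40) without T4. Type I interferon-response genes were lower in CD8 T-like cells (-0.68, or -0.22 without T4) and NK-like cells (-0.60, -0.87 to -0.42, percentile 0.040, 11 of 19 lower), and near vehicle in macrophage/monocyte-like cells (0.13, or -0.13 without cluster 3). They stood in regulatory T-like cells at 0.19 (0.09 to 0.38, percentile 99.84, 7 higher and 0 lower of 28), but at -0.06 without T3 and -0.05 with cells weighted equally.

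Macrophage-like cells were 11.5% of leukocytes after hu14.18-IL15 against 17.5%, a difference of -6.05 points (-7.78 to -4.30). It was -1.13 at resolution 0.6, -2.14 with response genes kept, -3.34 under the stricter filter, -10.8 with each library clustered on its own, -10.3 over all kept cells, -11.0 without T4 and -1.55 without clusters 5 and 6. Monocyte-like cells were 11.3% against 9.48%, a difference of 1.85 points (0.331 to 3.39) that was -3.68, 4.82, 0.781 and -0.703 over all kept cells, with each library clustered on its own, at resolution 0.6 and without T4. Neutrophil-like cells were 2.38% against 0.777%, a difference of 1.6 points (0.987 to 2.27) that was 0.0701 under the stricter filter, 0.240 over all kept cells, 1.01 at resolution 0.6 and 0.971 with response genes kept. CD4 T-like cells differed by -0.893 points (-1.58 to -0.204), plasma-like cells by -1.71 (-2.85 to -0.560) and plasmacytoid DC-like cells by -1.81 (-2.82 to -0.798), the last 2 by -3.60 and -3.08 over all kept cells. Without T4 these 3 differences were -1.56, -3.52 and -3.28. The ratio of CD8 T-like to regulatory T-like cells was 5.22 (4.48 to 6.12) against 6.76 (5.77 to 7.95), and 4.86 against 2.47 without T4, the opposite order.

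In NK-like cells 29 of 32 measured cell cycle genes were at least 1.5-fold higher after hu14.18-IL15, with a median of 2.45 (2.14 to 3.1, percentile 100), or 2.28 with the 4 genes absent from vehicle at their bound. Mki67 was at 299 against 9.17 CPM, log2 ratio 4.62 (3.24 to 6.51), Hist1h2ae at 4.75, or 1.82 without cluster T12, and Cdca8 and Hist1h3c, both absent from vehicle, were at least 17.7-fold and 10.9-fold higher, with 8 of 89 and 1 of 55 UMIs outside T12. Without T12, which held 20 cells, the list stood at 0.77 over 12 genes and Mki67 at 2.29. The cytotoxic list stood at 0.01 (-0.08 to 0.11, percentile 47.2, 3 higher and 1 lower of 18), or 0.03 without T12, against a median of -0.17 over all measured genes. Ccl3 was at 2.67 (1.47 to 4.17), Ifng at 94.8 against 27.5 CPM, log2 ratio 1.66 (0.67 to 2.80), and Prf1 at 538 against 700.0 CPM, log2 ratio -0.38 (-0.64 to -0.13). Mylip (ENSMUSG00000038175, chromosome 13, 45389742 to 45412022) was at -2.28 (-3.14 to -1.48), Lars2 at -1.90 and Ifi44 at -1.64. Cytokine receptor genes stood at -0.63 (4 genes, percentile 0.060), among them the common gamma chain gene Il2rg at -0.71 and Jak1 at -0.55. STAT3 targets stood at -0.37 (11 genes, percentile 2.1), STAT5 targets at -0.22 (10 genes, percentile 12.8), stress genes at 0.07 (16 genes, percentile 68.9) and ribosomal protein genes at 0.19 (20 genes, percentile 88.6), or 0.29 without T12.

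In CD8 T-like cells after hu14.18-IL15, Gzmb was at a log2 ratio of 0.78 (0.72 to 0.84), or 1.04 without T4, and the survival gene Bcl2 at 91.4 against 48.3 CPM, log2 ratio 0.92 (0.73 to 1.11), or 1.43 without T4. STAT5 targets had a median of 0.30 (0.14 to 0.44, percentile 99.99, 5 higher and 2 lower of 22), with Cish, a feedback inhibitor of this pathway, at 0.91 (0.63 to 1.2) and at 2.08 without T4. Ifitm1 (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), a membrane protein induced by interferon, was at 40.3 against 0.507 CPM, log2 ratio 6.06 (4.91 to 7.52), in 33 cells. The cell cycle inhibitor Cdkn1a was at 1.65 (1.31 to 2.00) and Mt1 at 1.37, or 0.84 without T4. Cell cycle genes stood at 0.44 (0.39 to 0.48, percentile 100, 13 of 40 higher) and at -0.17 without T4. The cytotoxic list stood at -0.06 (-0.11 to -0.01, percentile 17.6) and at 0.21 without T4, and inhibitory receptors at -0.05 (-0.20 to 0.04, percentile 39.1) and at 0.22 without T4.

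Type I interferon-response genes in CD8 T-like cells after hu14.18-IL15 had a median of -0.68 (-0.75 to -0.58, percentile 0, 21 of 32 lower), which was -0.22 with 7 of 31 lower without T4. Ifit1bl1 (ENSMUSG00000079339, chromosome 19, 34592891 to 34601956), an IFIT family gene, was at 7.68 against 31.3 CPM, Tent5a at a log2 ratio of -1.95 and the helicase gene Ddx60 at -1.76. Without T4 these 3 genes stood at -1.19, -1.18 and -0.81. MHC class I genes stood at -0.38 (-0.41 to -0.34, percentile 0, 3 of 17 lower), or -0.15 without T4. Naive and memory genes stood at -0.33 (15 genes, percentile 3.76), at -0.64 without T4 and at 0.07 at a clustering resolution of 1.6. Among them Tcf7 was at 7.49 against 27.5 CPM, log2 ratio -1.85 (-2.36 to -1.36), and the chemokine Xcl1 at -1.30, or -2.03 without T4. STAT3 targets stood at -0.08 (16 genes, percentile 33.1), or 0.16 without T4, and stress genes at -0.02 (20 genes, percentile 52.2), or 0.00 without T4. Ribosomal protein genes stood at -0.03 (20 genes, percentile 13.4), or -0.05 without T4 and 0.00481 when scaled by the median ratio.

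In regulatory T-like cells after hu14.18-IL15, effector genes stood at 0.12 (0.02 to 0.22, percentile 95.4, 3 higher and 3 lower of 22) but at -0.35 without T3 and at -0.34 with cells weighted equally. Cell cycle genes stood at -0.18 (-0.28 to -0.11, percentile 0.240, 3 of 40 lower) and STAT5 targets at -0.04 (23 genes, percentile 40.3), and without T3 at 0.24 and -0.23. Foxp3 was at 0.32 (0.03 to 0.60), Il10 at 1.84 (0.86 to 2.86) and Gzmb at 0.84 (0.50 to 1.18), or -0.31, 1.18 and 0.29 without T3. Ubash3b (ENSMUSG00000032020, chromosome 9, 41011098 to 41161697), a phosphatase that dampens T cell receptor signals, was at 1.06 (0.57 to 1.55) and the stress gene Ppp1r15a at 1.01, or 0.48 and 0.45 without T3. Gtf2h2 (ENSMUSG00000021639, chromosome 13, 100460218 to 100492579), a subunit of transcription factor TFIIH, had 2 UMIs against 52, log2 ratio -2.83 (-5.15 to -1.2). The proteasome assembly gene Psmg1 stood at -2.44 and the nuclear pore gene Nup43 at -1.83. Without T3 these 3 genes stood at -0.97, -1.41 and -0.65.

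In macrophage/monocyte-like cells type I interferon-response genes stood at 0.13 (0.05 to 0.16, percentile 77.3, 2 of 33 higher and 0 lower) after hu14.18-IL15, or 0.20 without clusters 5 and 6 and -0.13 without cluster 3 (percentile 0.565, 0 higher and 0 lower of 33), with Rsad2 at 1.12 (1.01 to 1.23) and the T cell chemokine Cxcl10 at 0.65, or 0.21 and 0.37 without cluster 3. Interferon-gamma response genes stood at 0.12 (0.08 to 0.18, percentile 74.4, 1 higher and 1 lower of 35), or 0.19 without clusters 5 and 6. Nos2 was at 1.45 against 52.5 CPM, log2 ratio -4.96 (-6.28 to -3.91), with UMIs in 6 cells, Fabp4 at -4.44 (-4.82 to -4.08), Gpnmb at -3.62 and Ctsl at -2.78. Complement and lipid-handling genes had a median of -0.53 (-0.55 to -0.47, percentile 0, 10 of 22 lower), or -0.62 in macrophage-like and 0.15 in monocyte-like cells alone, but C1qa and Apoe stood at 0.34 and 0.24 in macrophage-like cells. Vsig4 (ENSMUSG00000044206, chromosome X, 96247203 to 96293438), a complement receptor of resident macrophages, was at 20.7 against 0.761 CPM, log2 ratio 4.65 (3.74 to 5.70). Cbr2 was at 3.22, Cd163 at 2.90, Stab1 at 2.81 and the scavenger receptor Marco at 2.37 (2.23 to 2.52), or 3.09 without clusters 5 and 6. Cxcl2, a neutrophil chemokine, was at 3.23. Cxcl13 was at -3.76, and at 2.25 without clusters 5 and 6.

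MHC class II genes had a median of -0.40 (-0.49 to -0.34, percentile 0.040, 2 of 11 lower) in these cells after hu14.18-IL15, or -0.265 without cluster 3. M1-type genes stood at 0.03 (-0.07 to 0.22, percentile 34.4, 6 higher and 3 lower of 20), or 0.16 without clusters 5 and 6 and -0.17 without cluster 3, with Il1b at 1.13, or 0.65 without cluster 3. M2-type genes stood at 0.05 (-0.08 to 0.17, percentile 35.8, 6 higher and 8 lower of 24), or -0.04 without clusters 5 and 6 and 0.20 without cluster 3, with Arg1 at -0.96 (-1.13 to -0.78), or -2.02 without those clusters. Fc receptor genes stood at -0.05 (20 genes, percentile 3.42), or 0.03 without clusters 5 and 6 and -0.10 without cluster 3, with Fcgr1 at 0.41 and Fcgr4 at -0.39, or 0.05 without those clusters. Suppressive myeloid genes stood at 0.10 (20 genes, percentile 59.5), or 0.06 without them and 0.03 without cluster 3, and chemokines at 0.03 (21 genes, percentile 27.9), or 0.16 and -0.24. Glycolysis and hypoxia genes stood at 0.11 (22 genes, percentile 70.3), stress genes at 0.25 (23 genes, percentile 99.3) and ribosomal protein genes at 0.10 (20 genes, percentile 57.5), or 0.03, -0.09 and 0.17 without cluster 3. The macrophage/monocyte-like cells were shallower than in vehicle, with a median of 5018 UMIs in 652 cells against 12240 in 903.

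The comparison of hu14.18-IL21 with vehicle asks the same of the antibody carrying IL-21, which signals mainly through STAT3. NK-like cells were at 3.04% of leukocytes (2.48 to 3.67, 103 cells) against 2.78%, a difference of 0.255 points (-0.554 to 1.06) that was not detectable at this depth, and was 0.0844 with each library clustered on its own, -0.751 over all kept cells, -0.00331 without T12 and -0.494 without T4. CD8 T-like cells were 28.0% (26.5 to 29.5) against 36.4%, a difference of -8.39 points (-10.6 to -6.17), or -15.9 over all kept cells, that turned to 8.68 (6.57 to 10.8) without T4. Regulatory T-like cells were 6.63% (5.82 to 7.52) against 5.38%, a difference of 1.25 points (0.112 to 2.39) that became -1.06 points over all kept cells, 0.141 with each library clustered on its own and -0.180 without T4. Plasma-like cells were higher, at 9.13% against 6.43%, a difference of 2.71 points (1.43 to 3.99), or -0.639 points over all kept cells and 1.04 without T4. Prf1 was higher in NK-like and in CD8 T-like cells. Type I interferon-response genes were lower in CD8 T-like (-1.17, or -0.70 without T4), macrophage/monocyte-like (-0.73, or -0.38 without cluster 3) and NK-like cells (-0.64, -0.91 to -0.44, percentile 0.030, 10 of 18 lower). They stood in regulatory T-like cells at -0.07 (-0.16 to 0.10, percentile 14.1, 2 higher and 4 lower of 28), at -0.46 without T3, at -0.34 with cells weighted equally and at -0.15 to 0.03 in the other alternatives.

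Macrophage-like cells were 20.3% of leukocytes after hu14.18-IL21 against 17.5%, a difference of 2.75 points (0.883 to 4.62) that became -4.14 over all kept cells and -1.46 with each library clustered on its own. It was 5.70 under the stricter filter, 4.41 with response genes kept, 4.68 and 1.80 at resolutions 0.6 and 1.6, -1.93 without T4 and 6.93 without clusters 5 and 6. Monocyte-like cells were 7.01% against 9.48%, a difference of -2.46 points (-3.78 to -1.15), or 0.344 points with each library clustered on its own, -4.29 over all kept cells and -5.11 without T4. CD4 T-like cells were 3.39%, a difference of 1.03 points (0.228 to 1.84) that was -0.218 over all kept cells, -1.63 with each library clustered on its own and 0.413 without T4. Neutrophil-like cells were 3.51% against 0.777%, a difference of 2.73 points (2.06 to 3.45) that was 0.740 points under the stricter filter and 1.17 over all kept cells. Plasmacytoid DC-like cells differed by -1.87 points (-2.85 to -0.910), or -3.34 without T4, and the ratio of CD8 T-like to regulatory T-like cells was 4.22 (3.64 to 4.90), or 3.80 (3.28 to 4.43) without T4, where vehicle stood at 2.47.

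In NK-like cells after hu14.18-IL21 the cytotoxic list had a median of 0.21 (0.12 to 0.30, percentile 95.9, 4 higher and 3 lower of 17). Prf1 was at 1035 against 700.0 CPM, log2 ratio 0.56 (0.31 to 0.82), Ifng at 1.63 (0.54 to 2.84) and Xcl1 at 888 against 336 CPM, log2 ratio 1.39 (1.07 to 1.73). Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) was at 418 against 15.3 CPM, log2 ratio 4.52 (3.36 to 6.00), and the related chemokine Ccl4 at 3.33 (2.78 to 3.92), with 62.2% and 69.7% of their UMIs in 5 cells. Cell cycle genes stood at 2.83 (2.20 to 3.27, percentile 100, 16 of 19 higher), also with the 2 genes absent from vehicle at their bound, but at -0.12 over 7 genes without the 9 cells of T12. Mki67 was at 4.37 (2.95 to 6.28), or 1.32 without T12, Hist1h2ae at 4.08, or 1.09 without T12, and Cdca8 at least 16.1-fold higher, with 4 of 42 UMIs outside T12. Ifi203 (ENSMUSG00000039997, chromosome 1, 173920407 to 173942672), an interferon-induced DNA sensor family gene, was at -1.94 (-2.72 to -1.23), Ube3a at -1.70 and Oip5os1 at -1.55. STAT3 targets stood at 0.08 (8 genes, percentile 74.7), or 0.20 without T12, with Stat3 at -0.93, and STAT5 targets at -0.21 (10 genes, percentile 16.8), or -0.03 without T12. Cytokine receptor genes stood at -0.34 (4 genes, percentile 5.25), stress genes at 0.37 (15 genes, percentile 99.9), and ribosomal protein genes at 0.15 (20 genes, percentile 85.5).

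In CD8 T-like cells after hu14.18-IL21, Prf1 was at 782.5 against 508.5 CPM, log2 ratio 0.62 (0.56 to 0.68), or 0.92 without T4. Ifng was at 0.27 (0.18 to 0.37), or 0.69 without it, and Gzmb at 0.11 (0.04 to 0.18), or 0.37 without T4 and -0.01 with cells weighted equally. The cytotoxic list stood at -0.14 (-0.17 to -0.11, percentile 2.84, 5 higher and 4 lower of 21), at 0.16 without T4 and at 0.08 with every gene of at least 1 UMI. Calcb (ENSMUSG00000030666, chromosome 7, 114718643 to 114723365), encoding a calcitonin gene-related peptide, was at 21.5 against 3.25 CPM, log2 ratio 2.70 (2.13 to 3.30). It was followed by Mt1 at 1.56, or 1.04 without T4, and Supt3 at 1.10. The transcription factor Maf was at 1.29 (0.84 to 1.74), within STAT3 targets at -0.01 (16 genes, percentile 48.9), or 0.19 without T4. Cell cycle genes stood at 0.19 (0.15 to 0.25, percentile 99.9, 1 of 40 higher) and at -0.37 without T4, and inhibitory receptors at -0.05 (-0.10 to 0.08, percentile 35.7) and at 0.29 without T4.

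Type I interferon-response genes in CD8 T-like cells after hu14.18-IL21 had a median of -1.17 (-1.36 to -1.07, percentile 0, 30 of 32 lower), or -0.70 with 18 of 30 lower without T4. Ifit1 was at -2.60 (-3.00 to -2.23), Ifit1bl1 at -2.54 and Rsad2 at -2.64. Ly6c1 (ENSMUSG00000079018, chromosome 15, 75044018 to 75048830), a surface protein of memory and interferon-exposed T cells and a leading gene of T4, was at 46.5 against 343 CPM, log2 ratio -2.88 (-3.06 to -2.69), and -2.34 without T4. MHC class I genes stood at -0.40 (-0.43 to -0.34, percentile 0, 5 of 17 lower), or -0.14 without T4, with B2m at -0.74. STAT5 targets stood at 0.13 (23 genes, percentile 94.1), or 0.32 without T4, and naive and memory genes at -0.09 (14 genes, percentile 35.4), or -0.22 without T4. Stress genes stood at -0.04 (20 genes, percentile 33.8), or 0.04 without T4, and ribosomal protein genes at 0.16 (20 genes, percentile 95.7).

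In regulatory T-like cells after hu14.18-IL21, 14 of 40 cell cycle genes were at least 1.5-fold lower and 0 higher, with a median of -0.40 (-0.50 to -0.31) at percentile 0, among them Cdk1 at -1.05 and Mki67 at -0.42. The list median was -0.27 at a clustering resolution of 1.6 and turned to 0.14 without T3, where 3 of 16 genes were higher and 0 lower and these 2 genes stood at -0.62 and -0.14. Effector genes stood at 0.22 (0.14 to 0.40, percentile 98.0, 5 higher and 1 lower of 22) but at -0.20 without T3 and at -0.22 with cells weighted equally. Gzmb was at 1.28 (0.98 to 1.59), Il10 at 1.71 (0.72 to 2.72), and the ectonucleotidase Entpd1 at 1.09, or 0.58, 0.74 and 0.59 without T3. STAT5 targets stood at 0.23 (23 genes, percentile 97.8, 6 higher and 3 lower) and Foxp3 at 0.43 (0.16 to 0.70), or -0.00 and -0.18 without T3. Nr4a2 (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003), a nuclear receptor induced by T cell receptor signals, was at 83.4 against 17.4 CPM, log2 ratio 2.24 (1.66 to 2.85), Plek at 1.98 and the cold-inducible RNA-binding gene Cirbp at 1.42. Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014) was at -2.37 (-3.46 to -1.44), Fosb at -2.18 and Aimp2 at -1.80, or -0.97, -1.33 and -0.74 without T3.

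In macrophage/monocyte-like cells 22 of 33 type I interferon-response genes were lower after hu14.18-IL21, with a median of -0.73 (-0.76 to -0.67) at percentile 0, or -0.38 with 8 of 33 lower without cluster 3, among them Isg20 at -1.47, or -0.95 without cluster 3, and Ifit1 at -1.28. Interferon-gamma response genes stood at 0.04 (0.01 to 0.10, percentile 45.0, 2 higher and 4 lower of 35), or -0.03 when scaled by the median ratio and 0.26 without cluster 3 (percentile 99.8, 7 higher and 2 lower of 34). Retnla, an M2-type gene, was at 33.1 against 901 CPM, log2 ratio -4.76 (-4.94 to -4.59), Fabp4 at -3.96, Nos2 at -2.22 (-2.55 to -1.91), with UMIs in 22 cells. Complement and lipid-handling genes stood at -0.36 (-0.38 to -0.31, percentile 0, 4 higher and 8 lower of 22), or -0.54 without clusters 5 and 6, -0.40 in macrophage-like and 0.09 in monocyte-like cells alone, but C1qa and Apoe stood at 0.65 and 0.63 in macrophage-like cells. Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165) had 1 UMI after hu14.18-IL21 against 134 CPM in vehicle, and the lipoxygenase gene Alox15 was at least 181-fold lower. Both mark cluster 5, of which the hu14.18-IL21 library held 0 cells and vehicle 20, and Cxcl13, at -7.93 (-10.98 to -6.07), stood at -0.98 without clusters 5 and 6. Adamdec1 was at 5.12 (4.29 to 6.09), the prostaglandin-degrading Hpgd at 4.04 (3.38 to 4.79), Stab1 at 3.05, Cxcl2 at 3.64 and the immediate early gene Egr1 at 2.52. The neutrophil elastase gene Elane (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215) was highest by the naming rule, at 20.2 against 0.0761 CPM, but all of its UMIs came from 1 cell of cluster 3.

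Glycolysis and hypoxia genes in these cells stood at 0.53 (0.42 to 0.59, percentile 100, 9 of 23 higher) after hu14.18-IL21, with the lactate exporter Slc16a3 at 1.22 and Vegfa at 1.96, and stress genes at 0.48 (23 genes, percentile 100). M2-type genes stood at 0.21 (0.06 to 0.34, percentile 97.2, 11 higher and 9 lower of 25), at -0.08 without clusters 5 and 6 and at -0.17 with genes of at least 100 UMIs. Mrc1 was at 0.35, or 0.19 without those clusters, Arg1 at -0.78 and Ccl17, absent after treatment, at least 102-fold lower. M1-type genes stood at -0.00 (-0.10 to 0.10, percentile 26.2, 4 higher and 5 lower of 20), or 0.06 without clusters 5 and 6 and 0.04 without cluster 3. MHC class II genes stood at 0.05 (-0.02 to 0.09, percentile 54.3), or -0.12 without clusters 5 and 6 and 0.14 without cluster 3, and suppressive myeloid genes at 0.22 (20 genes, percentile 96.7), or 0.04 without cluster 3 and -0.02 with genes of at least 100 UMIs. Fc receptor genes stood at 0.05 (20 genes, percentile 50.2), or 0.17 without clusters 5 and 6, 0.19 without cluster 3 and -0.03 when scaled by the median ratio. Chemokines stood at 0.14 (21 genes, percentile 85.9), or 0.22 without clusters 5 and 6 and 0.48 without cluster 3, and ribosomal protein genes at 0.07 (20 genes, percentile 74.2), or 0.13 without those clusters and -0.01 when scaled by the median ratio.

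Shares of cells with a transcript were compared after each cell was thinned to 1000 UMIs. Cells too shallow for this numbered 2, 9, 5 and 0 among NK-like cells in vehicle and after the IL2, IL15 and IL21 fusions, 9, 7, 13 and 16 among CD8 T-like, 1, 8, 15 and 7 among regulatory T-like and 2, 5, 3 and 3 among macrophage/monocyte-like cells. Ifng was found in 2.20% of vehicle NK-like cells (0.267 to 7.72) and in 7.61% (4.77 to 11.4), 11.2% (7.05 to 16.6) and 8.74% (4.07 to 15.9) after treatment, with overlapping intervals, and unthinned in 9.68%, 20.7%, 19.7% and 20.4%. The share in CD8 T-like cells was 22.2% in vehicle and 15.9%, 20.4% and 26.5% after treatment, unthinned 59.8%, 49.0%, 47.8% and 55.4%, and without T4 17.7%, 15.3%, 20.5% and 26.8%. Macrophage/monocyte-like cells, a gauge of free RNA, had 0.333%, 0.219%, 0.154% and 1.08%. Foxp3 was found in 24.6% of vehicle regulatory T-like cells and in 18.0%, 24.9% and 23.4% after treatment, unthinned in 67.8%, 48.6%, 47.5% and 49.8%, and without T3 in 34.2%, 23.5%, 26.4% and 25.4%, against at most 0.308% of macrophage/monocyte-like cells. Gzmb in NK-like cells stood at 22% in vehicle and 31.9%, 29.3% and 30.1% after treatment, and unthinned at 39.8%, 48.4%, 48.2% and 39.8%, against at most 0.555% of macrophage/monocyte-like cells. The share in CD8 T-like cells was 30.4% in vehicle and 26.3%, 41.2% and 26.4% after treatment, unthinned 65.1%, 55.1%, 69.0% and 53.9%, and without T4 26.4%, 26.5%, 40.5% and 25.6%. Arg1 was found in 6.88% of vehicle macrophage/monocyte-like cells and in 5.36%, 4.16% and 2.60% after treatment, unthinned in 19.8%, 9.13%, 9.36% and 7.45%, and without clusters 5 and 6 in 8.80%, 2.94%, 3.11% and 2.94%, or 6.40% after hu14.18-IL15 without cluster 3, against at most 0.331% of CD8 T-like cells. After hu14.18-IL2 this order runs against the Arg1 level in CPM, so none is read from it. Median depths before thinning ran from 2318 to 3418 UMIs in NK-like, 4338 to 6084 in CD8 T-like, 2469 to 5874 in regulatory T-like and 5018 to 12240 in macrophage/monocyte-like cells.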

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

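Both clusters were picked after the data were seen, as unnamed cells used in no comparison and with a larger share of a treated library than of vehicle. Unnamed cluster 20 was 2.29% of kept cells after hu14.18-IL15 (1.97 to 2.65) and 2.60% after hu14.18-IL21 (2.22 to 3.01), against 1.37% in vehicle (1.04 to 1.79) and 1.14% after hu14.18-IL2. Its leading genes included AY036118, Gm42418 and Ank3, and Prc1, H1fx and H1f0 shared with tumor-like cluster 13. Of markers of its closest class, erythroid, 0 were detected, and its cells were shallow, with a median of 1226 UMIs in vehicle and 943 and 801.5 after the IL15 and IL21 fusions. Unnamed cluster T11 was 2.65% of leukocytes after hu14.18-IL21 (2.14 to 3.25) against 1.2% in vehicle (0.856 to 1.63), with T cell genes such as Nkg7, Ifng and Ccl5 beside the macrophage genes C1qa, C1qb and Apoe. No biological explanation was tested for either cluster.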

How the results depend on the processing

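Leaving out clusters, the single doublet limit and the other ranking of leading genes were chosen after the data were seen. No paired analysis was possible because each group is 1 library, so that the groups compared share fewer than 2 replicate numbers and no test was run. A value is said to have moved where it left its own counting interval. For each value below the cause was not tested, except where the alternative by its construction leaves out cells or genes or changes the denominator. Shares are given as differences from vehicle in percentage points and lists as median log2 ratios, in the order hu14.18-IL2, hu14.18-IL15, hu14.18-IL21 where 3 are given and otherwise marked IL2, IL15 or IL21.

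With doublet calls kept or the single limit, all 39 main and 63 further list values stayed within their intervals. The tumor-like shares of treated libraries moved, with doublet calls kept, to 45.0%, 57.4% and 42.3%. With clusters 12, 13, 16 and 23 not counted as tumor but kept among all cells, the shares were 9.44% in vehicle and 13.9%, 16.9% and 9.40% after treatment, and with them left out of both parts 9.84%, 20.6%, 29.1% and 14.3%. The ratio of CD8 T-like to regulatory T-like cells stayed within its interval in these 2 settings, under the stricter filter and at resolution 1.6. Without T4 it moved in vehicle to 2.47, and without T3 it moved to 10.05 in vehicle and 2.99, 7.31 and 5.27 after treatment. At resolution 1.6 all 24 main share differences also did. Under the other ranking the shares compared cannot move by construction, which says nothing of their stability. With 10 added to each sum, 454 gene values stayed within their intervals and 41 moved. Of 24 shares of positive cells, 23 moved unthinned and 23 at 2000 UMIs, as did 2 of 8 without T4, 0 of 8 without T12, 2 of 4 without T3, 2 of 4 without clusters 5 and 6 and 2 of 4 without cluster 3.

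With all kept cells as denominator, NK-like cells differed by 2.45, 0.202 and -0.751 points, CD8 T-like cells by -17.6, -17.0 and -15.9, and regulatory T-like cells by 2.25, -1.93 and -1.06. Macrophage-like cells differed by -2.87, -10.3 and -4.14, monocyte-like cells by -4.29, -3.68 and -4.29, and neutrophil-like cells by 0.857, 0.240 and 1.17. After hu14.18-IL15 plasma-like cells differed by -3.60 and plasmacytoid DC-like cells by -3.08. After hu14.18-IL21 plasma-like cells differed by -0.639, CD4 T-like cells by -0.218 against 1.03 over leukocytes and mixed T-like cells by -0.490 against 2.02. CD4 T-like cells differed by -0.216 after hu14.18-IL2, against 1.04 over leukocytes.

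With each library clustered on its own, macrophage-like cells differed by 1.95, -10.8 and -1.46 points and monocyte-like cells by -0.711, 4.82 and 0.344. CD8 T-like cells differed by -9.27 (IL2) and 3.81 (IL15), regulatory T-like cells by 5.78 (IL2) and CD4 T-like cells by -1.63 (IL21). With response genes kept, CD8 T-like cells differed by -6.12 (IL21), macrophage-like cells by -2.14 (IL15), neutrophil-like cells by 0.971 (IL15) and 1.94 (IL21), and CD4 T-like cells by -0.840 (IL2). At resolution 0.6 macrophage-like cells differed by -1.13 (IL15) and 4.68 (IL21), neutrophil-like cells by 1.89 (IL21) and mixed T-like cells by 0.151 (IL2) against -1.12 at resolution 1.0. Under the stricter filter macrophage-like cells differed by 8.17, -3.34 and 5.70 and neutrophil-like cells by -0.200, 0.0701 and 0.740.

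Scaling by the median ratio left 29 of the 39 main list values within their intervals. NK cytotoxic genes stood at 0.34 (IL2) and 0.18 (IL15), CD8 cell cycle genes at 0.55 (IL2) and CD8 ribosomal genes at 0.00481 (IL15). In macrophage/monocyte-like cells type I interferon genes stood at -1.08, 0.0406 and -0.81, and interferon-gamma genes at -0.0934, 0.0374 and -0.0339. There, after hu14.18-IL21, MHC class II genes stood at -0.0293, Fc receptor genes at -0.0276 and ribosomal genes at -0.0110. The stricter filter left 35 of the 39 within. In the same cells it gave interferon-gamma genes at -0.0599, 0.0199 and -0.0463, and after hu14.18-IL21 type I interferon genes at -0.82 and Fc receptor genes at -0.0191. It gave chemokines at -0.00102 (IL2) and Cxcl9 at -0.0249 (IL15).

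Weighting cells equally moved 16 and turned 3 of the 39. NK cell cycle genes stood at 2.37, 1.76 and 1.45 and CD8 cell cycle genes at 0.88, 0.81 and 0.38. In CD8 T-like cells, cytotoxic genes stood at -0.0200 (IL21), type I interferon genes at -1.78 (IL2), inhibitory receptors at -0.42 (IL2) and 0.13 (IL21), and ribosomal genes at 0.0299 (IL15). In regulatory T-like cells, cell cycle genes stood at 0.24 (IL2) and effector genes at -0.47, -0.34 and -0.22 and type I interferon genes at -0.0535 (IL15). In macrophage/monocyte-like cells type I interferon genes stood at -1.12 (IL2) and -0.81 (IL21), interferon-gamma genes at -0.0515 (IL2) and 0.00578 (IL21), M2-type genes at 0.35 (IL21) and chemokines at -0.26 (IL2). Of single genes, 353 stayed within, 137 moved and 5 turned. These 5 were Gzmb in CD8 T-like cells at -0.00924 (IL21), Cd274 at 0.18 (IL15) and Fcgr4 at 0.0143 (IL2) in macrophage/monocyte-like cells, and Mki67 at 0.0816 (IL2) and Tfrc at 0.15 (IL15) in regulatory T-like cells.

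At resolution 1.6 CD8 cytotoxic genes stood at -0.11 (IL21), CD8 cell cycle genes at 0.40 (IL2) and 0.37 (IL15), CD8 type I interferon genes at -1.39 (IL21) and CD8 naive and memory genes at 0.0697 (IL15). In regulatory T-like cells cell cycle genes stood at -0.27 (IL21) and effector genes at 0.00649 (IL15) and 0.0980 (IL21). Measured from 1 UMI, NK cell cycle genes stood at 1.78 and CD8 cytotoxic genes at 0.0823, both for hu14.18-IL21. Measured from 100 UMIs, NK cell cycle genes stood at 3.73, 3.28 and 2.09 and CD8 cytotoxic genes at -0.51 (IL2). In macrophage/monocyte-like cells after hu14.18-IL21, M2-type genes then stood at -0.17 and suppressive myeloid genes at -0.0244.

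With T4 left out of the class and the leukocytes, CD8 T-like cells differed by 6.62, 16.9 and 8.68 points, regulatory T-like cells by 6.18, 0.0319 and -0.180, macrophage-like cells by 0.214, -11.0 and -1.93, and monocyte-like cells by -5.22, -0.703 and -5.11. Plasma-like cells differed by -4.92, -3.52 and 1.04, and plasmacytoid DC-like cells by -5.09, -3.28 and -3.34. NK-like cells differed by 4.70 (IL2) without T12, regulatory T-like cells by 4.98 (IL2) without T3, and macrophage-like cells by -1.55 (IL15) and 6.93 (IL21) without clusters 5 and 6.

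Without T3, regulatory T cell cycle genes stood at 0.23, 0.24 and 0.14 and effector genes at -0.44, -0.35 and -0.20, so that 5 of these 6 values turned, and type I interferon genes at -0.0602 (IL15). Without T12, NK cell cycle genes stood at 0.74, 0.77 and -0.12. Without T4, CD8 cytotoxic genes stood at 0.21 (IL15) and 0.16 (IL21), cell cycle genes at -0.20, -0.17 and -0.37, type I interferon genes at -1.40, -0.22 and -0.70, and inhibitory receptors at -0.39, 0.22 and 0.29. Without clusters 5 and 6, MHC class II genes stood at -0.59, -0.50 and -0.12. Type I interferon genes then stood at 0.20 (IL15), interferon-gamma genes at 0.19 (IL15), Fc receptor genes at 0.0260 (IL15), M1-type genes at -0.0297 (IL2), chemokines at -0.0733 (IL2) and M2-type genes at -0.0805 (IL21). Without monocyte cluster 3, type I interferon genes stood at -0.73, -0.13 and -0.38, MHC class II genes at -0.39, -0.265 and 0.14, interferon-gamma genes at 0.28 (IL2) and 0.26 (IL21), M1-type genes at 0.0251 (IL2) and -0.17 (IL15), M2-type genes at 0.20 (IL15) and stress genes at -0.0897 (IL15).

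Some alternatives gave no value. Resolution 0.6 had no regulatory T-like, CD4 T-like or conventional DC 1-like cluster, resolution 1.6 no CD4 T-like or mixed T-like cluster, and response genes kept or the other ranking no mixed T-like cluster. Clustered alone, no library had a mixed T-like cluster, hu14.18-IL15 had no regulatory T-like cluster, hu14.18-IL2 and hu14.18-IL15 no CD4 T-like cluster, and hu14.18-IL2 and hu14.18-IL21 no conventional DC 1-like cluster. Depth limits the small classes: NK-like cells numbered 93 in vehicle, with a median of 3418 UMIs, and plasmacytoid DC-like cells 51 after hu14.18-IL2.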

Other observations

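The lists and the 3 clusters used for tumor cells, the values without T3, cluster 3 or 4 tumor-like clusters, the test of interferon genes against hu14.18-IL2 alone, and the test of shares outside CD8 T-like cells were chosen after the results were seen. Neuroblastoma-like cells also differed between libraries. Type I interferon-response genes in them had a median log2 ratio to vehicle of -1.27 after hu14.18-IL2 (-1.43 to -1.22), -1.38 after hu14.18-IL15 (-1.49 to -1.32) and -1.65 after hu14.18-IL21 (-1.75 to -1.54). Of 33 measured genes, 30, 31 and 31 were at least 1.5-fold lower and 0 higher. MHC class I presentation genes, which show antigen to CD8 T cells, stood at -1.22 (16 of 17 lower), -1.37 (17 lower) and -1.45 (17 lower). Interferon-gamma response genes stood at -1.32, -1.49 and -1.68, with 29, 30 and 29 of 35 lower and 1, 1 and 3 higher. Cxcl10, a chemokine that draws T cells, was at 474 CPM in vehicle and at 72.8, 53.5 and 56.2 CPM after the IL2, IL15 and IL21 fusions.

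Glycolysis and hypoxia genes in these cells stood at 0.61 (11 of 22 higher), 0.46 (9 higher) and 0.83 (13 higher), and cell cycle genes at -0.0228, -0.20 and -0.0803, or -0.18, -0.31 and -0.29 within clusters 9, 11 and 12. Of 541 vehicle tumor-like cells, 474 lay in clusters 9, 11 and 12, while most treated ones lay in others. Within those 3 clusters type I interferon genes stood at -1.50, -1.58 and -1.60, MHC class I genes at -1.33, -1.51 and -1.45, and glycolysis and hypoxia genes at 0.60, 0.54 and 0.88. C1qa, a gauge of free macrophage RNA, was at 16.4 CPM in vehicle tumor-like cells and at 25.5, 18.5 and 25.7 CPM in treated ones. Vehicle tumor-like cells were deeper, with 26960333 UMIs in 541 cells against 51997928 in 2779 after hu14.18-IL2.

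Cluster T4 held 23.1% of vehicle leukocytes and at most 2.74% of treated ones. Free RNA of monocytes, which also express Ly6c2, is argued against: Ly6c2 stood in vehicle T4 at 0.607 of its level in monocyte-like cells, and the median of the other markers was 0.0137 of that ratio. An interferon difference of the whole vehicle library was to be rejected if at most 6 of 12 class and treatment values lay below -0.3, but 8 did, so it stays open. Type I interferon genes were lower after each treatment in NK-like cells (-0.83, -0.60 and -0.64) and in tumor-like cells, and against hu14.18-IL2 in 4 of 4 classes, but after hu14.18-IL15 stood at 0.19 (0.09 to 0.38) in regulatory T-like cells, or -0.06 without T3, and 0.13 (0.05 to 0.16) in macrophage/monocyte-like cells, or -0.13 without cluster 3. With 1 library per group, a feature of the vehicle pool and a cell state that treatment alters cannot be told apart here.

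Tumor-like cells were 13.5% of kept vehicle cells, 0.310 of the share in the lowest treated library. With clusters 12, 13, 16 and 23 not counted as tumor it was 9.44% against 9.40% after hu14.18-IL21, and with them left out of both parts 9.84% against 14.3%. The mitochondrial filter as the cause is argued against, since over every barcode the shares were 11.8%, 39.9%, 54.0% and 39.7%, a ratio of 0.298 to the lowest treated library. Bead selection or tumor size that differed between the pools cannot be told apart from treatment, because each group has 1 library.

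NK-like and regulatory T-like cells held larger shares of leukocytes after hu14.18-IL2 than in vehicle. The lower CD8 T-like share alone is argued against, since outside CD8 T-like cells the NK-like share was still 2.80-fold and the regulatory T-like share 2.05-fold that of vehicle. No biological explanation or difference between the pools was tested.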
